A study of Mus musculus with 14 samples.

How the data were processed

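The data are gene expression values from 14 arrays of the Affymetrix Mouse Genome 430 2.0 type, in 3 cell sets: 6 arrays of spleen DCs, 4 of RAW264.7 cells and 4 of bone marrow Gr1/CD11b cells. Groups were taken from the sample titles and descriptions. The heterozygous Leiden DC sample carries a homozygous genotype tag beside a heterozygous title, description and source, and was taken as heterozygous. RNA was amplified in 2 cycles from 100 ng and labelled with biotin, per the labels' protocols, so that faint transcripts pass through more amplification than in a single cycle. The deposited values are log2 signals, which the authors made with Affymetrix Expression Console and RMA, per the submitters' processing notes; versions are not given in the sources used here. RMA corrects background, quantile normalizes and summarises probes on the log2 scale. The distributions of the 3 sets differ, so differences were computed within a set only; where values of separate sets stand side by side, they are described and not compared. Each array held 45037 probe sets, with 0 control rows named AFFX, so control-based measures of RNA quality could not be computed. No 2 arrays held identical values. Arrays have no read depth: precision is limited by their number and, for faint probe sets, by background.

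Genes were named through the platform annotation: 34945 probe sets had 1 gene, 932 several and 9160 none in it, and only the first kind was used. Of these, 34741 matched a RefSeq gene of the GRCm38.p6 assembly by Entrez ID, and the others kept the annotation's symbol, which gave 18193 genes. A gene was represented by its probe set of highest mean over the arrays of its set. It was measured in a comparison if it exceeded the array's median over all probe sets on at least 1 array compared. These values and differences need no pseudocount, being log2 already.

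The bone marrow columns could not be joined to the IDs, as the report describes. The planned gene names, gene lists (camera, with fry as an alternative) and choices between probe sets were therefore not carried out for them, and rows were tested without names. A row was tested if it exceeded the array's median on at least 2 of 4 arrays. limma (lmFit and eBayes) was fitted to these 4 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each array was a pool from different animals as far as the labels say; where pools shared animals or handling the p-values would reflect only the spread between these samples. The replicate numbers carry no stated pairing, so the main fit had no block. The depleted-transfer sample titled 2 is called replicate 1 in its source name; the title was followed, and the block fit rests on it.

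The 9 planned comparisons of single arrays were not tested against replicates. After the values were seen, limma was fitted to the 6 DC arrays with LPS, aPC and genotype as additive effects, for genes above the floor on at least 2 arrays. This fit leaves 1 residual degree of freedom, which is the difference between the genotypes' aPC effects; the same model leaves 0 for the 4 RAW264.7 arrays. A gene was counted as differing at a log2 difference of at least 1, which is 2-fold. Of the 28 gene lists fixed before the data were examined, those with at least 4 measured members were summarised by their median difference, its percentile among 10000 random lists of the same size drawn within 10 bins of mean expression, and the number of members past 2-fold. A list is described where it lay at or outside the percentiles 2.5 and 97.5 with a median of at least 0.5 in size, the latter limit set after the values were seen. These percentiles describe the arrays and are not p-values. A comparison of aPC effects between genotypes was the difference of the differences.

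Genes were named by a rule fixed before the data were examined: per comparison, the 10 highest and the 10 lowest differences of at least 1 among measured genes whose median over all their probe sets had the same sign; from each list described, up to 2 members each way with the largest differences; and Procr, Thbd, F3, F5, F2r and F2rl1 where measured. No probe set was assigned to F2rl1 in the annotation used here. Names of predicted or unnamed genes were passed over, and 4 further comparisons, chosen after the values were seen, are named so where they appear.

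The alternatives fixed beforehand were no floor, a floor at the array's 75th percentile, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, a further quantile normalization within the set, centring each array on its median over the measured genes, a threshold of 1.5, random lists without matching, LPS lists of the 200 highest genes and, for the bone marrow arrays, a replicate block, each array left out, eBayes with trend and robust, and an adjusted p under 0.1. With no replicates in 2 sets, the SD of a difference between single arrays (0.10) was taken from the bone marrow replicates to judge whether a value moved. Agreement between 2 probe sets of a gene, LPS lists from other arrays than planned, genes lower with LPS and counts without neutrophil, B cell and macrophage list members, and differences with arrays under the floor set to the floor, were added after the values were seen.

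The calculations were tested on simulated data. In data simulated for the bone marrow comparison over 22929 rows, limma recovered 68.0% of rows changed by 0.5 on the log2 scale and 100% of those changed by 1, 2 or 3, with 13 unchanged rows among 197 calls. In data simulated for the DC comparisons over 11249 genes, 91 of 100 lists of 20 genes shifted by 0.5 fell outside the random range. Of unshifted lists, 6 of 100 did. For the RAW264.7 comparisons over 10998 genes the numbers were 100 and 1. Simulated genes varied independently, whereas members of a real list can move together on an array, so these rates may not hold for real lists. In data simulated for the additive fit, limma recovered 28.5% of genes changed by 1 on the log2 scale, 97.5% of those changed by 2 and 100% of those changed by 3 or 4, with 64 unchanged genes among 716 calls. That simulation changed 200 genes at each size and drew its noise from the fit's own moderated variances. The real fit gave 19 calls for aPC, and so a stricter cut-off. These recovery rates therefore do not describe the real fit. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, in R 4.3.3 with limma 3.58.1, and plots with matplotlib 3.10.9.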

Results

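Gene expression was measured on 14 mouse arrays from 3 cell sets, all concerned with lipopolysaccharide (LPS), activated protein C (aPC) and factor V. aPC is a plasma protease that inactivates clotting factor Va and also signals to cells through the endothelial protein C receptor, the product of Procr. Factor V Leiden is a form of factor V that resists this inactivation. The first set comprised 6 arrays of CD11c+ spleen dendritic cells (DCs), each hybridised with RNA pooled from 6 mice. Wildtype mice were untreated controls, were given LPS at 40 mg/kg, or were given LPS and then 10 µg of a signalling-selective aPC variant, and the spleens of the treated mice were taken after 16 h. Homozygous Leiden mice contributed an LPS array and an LPS-aPC array, and heterozygous Leiden mice an LPS array, whose dose is not given in the sources used here. The second set comprised 4 arrays of RAW264.7 cells, a mouse macrophage-like line, cultured for 3 h in medium with 10% plasma, each array holding a pool of 3 cultures. These were a control, LPS alone, and LPS with aPC, each at 100 ng/mL, in normal plasma, and the same mixture in plasma of homozygous Leiden mice. The dose of LPS alone is not given in the sources used here. The third set comprised 4 arrays of bone marrow Gr1/CD11b cells, 2 per group, each from 4 pooled animals. They were taken 7 days after infection with Staphylococcus aureus from heterozygous Leiden mice without EPCR on blood cells, which had received wildtype CD11c+ splenocytes and bone marrow cells, either complete or depleted of EPCR/F4/80-positive cells.

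In the DC and RAW264.7 sets each condition had 1 array, so no difference between 2 of those arrays was tested against replicates; a joint fit of the DC arrays, chosen after the values were seen, is given apart. In what follows, a gene or list described as higher or lower in these sets was so on the arrays compared, and all differences are on the log2 scale. Only the bone marrow groups had replicates: by the same 2-fold rule, 14 of 23214 rows differed between the wildtype-transfer arrays and 0 of 23018 between the depleted-transfer arrays. The number of arrays limits the precision of every value. Array medians lay between 4.50 and 4.66 in the DC set and between 4.85 and 4.87 in the RAW264.7 set. Agreement between probe sets of the same gene gave an internal measure of precision. The differences of a gene's first and second probe set correlated across genes at 0.54 for the DC LPS response and 0.76 for the RAW264.7 LPS response, over 4973 and 5208 genes, which are not independent replicates. A value at or under the detection floor, the array's median, holds mostly background, so a difference from such a value has no firm size.

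The first comparison set spleen DCs of LPS-treated wildtype mice against those of untreated mice. The genes furthest above the control in the LPS array included Saa3, an acute-phase serum amyloid, at 8.17, Lcn2, which binds iron-loaded siderophores, at 7.61, and the metallothionein Mt2 at 6.09. Ifng (interferon gamma) stood at 6.58, Il2ra (the alpha chain of the interleukin 2 receptor) at 5.70 and Gzmb (granzyme B) at 5.43. The fixed list of T cell markers had a median of -0.0175, inside the range of random lists. The fixed list of NK cell markers, which includes Gzmb, had a median of 1.31, above that range. H2-Ob, a subunit of the class II chaperone DO, was lower at -5.71 and Tlr3, the sensor of double-stranded RNA, at -5.21. The remaining genes with the highest differences were Ramp3 at 7.13, Igha (the IgA heavy chain) at 5.96, Abtb2 at 5.49 and Car13 at 5.46. The remaining genes with the lowest were Bex6 at -6.13, Tvp23b at -5.63, Rab32 at -5.62, Hps3 at -5.28, Plbd1 at -5.27, Ptger3, a prostaglandin E2 receptor, at -5.26, Nxpe4 at -5.25 and Otulinl at -5.23. Of these 20 genes, 13 had an array at or under the floor; with the control set to its floor, Saa3 stood at 8.12, Lcn2 at 6.255, Ramp3 at 5.79 and Il2ra at 4.23. With the mean of a gene's probe sets Abtb2 came to 2.74, Hps3 to -2.66 and Ptger3 to -2.49.

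Interferon-stimulated genes were higher as a group: 29 of 36 measured members were at least 2-fold higher and 0 lower, with a median of 2.47, led by Oasl1 at 5.23 and the chemokine Cxcl10 at 5.02. DC maturation genes had a median of 2.35 with 14 of 19 at least 2-fold higher, among them Cd70 at 4.01 and the homing receptor Ccr7 at 3.96. NF-kB targets and feedback genes had a median of 1.58, with 16 of 25 at least 2-fold higher, including Tnfaip2 at 3.95. Inflammatory cytokines and chemokines had a median of 1.47 but went both ways: Ccl22 stood at 3.79 and Cxcl3 at 3.75, while Il12b stood at -1.93 and Il18 at -1.36. Among protein C, protease-activated receptor and coagulation genes the median was 1.28, with Sphk1, which makes sphingosine 1-phosphate, at 5.13, its receptor S1pr3 at 3.75 and F2r, the receptor PAR1, at 2.64, against -2.87 for Serpinb2. With the mean of probe sets Tnfaip2 came to 2.38, S1pr3 to 1.98 and Il12b to -0.95; with an array under the floor set to it Cxcl3 came to 1.14, Serpinb2 to -0.65 and Il12b to -0.42. Procr itself differed by 0.60, and Thbd, F3 and F5 lay under the detection floor on both arrays.

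Class II presentation genes were lower, with a median of -1.82 and 9 of 13 at least 2-fold lower, H2-DMb2 at -3.31 among them, while Lgmn was higher at 1.37. Conventional DC markers had a median of -2.12, with 12 of 17 at least 2-fold lower and 0 higher, Xcr1 reaching -4.10. Cell cycle genes had a median of -1.67, with 22 of 27 at least 2-fold lower, among them Bub1 at -3.98 and Rrm2 at -3.71. Pattern recognition genes had a median of -0.90: Tlr1 stood at -3.03 and Tlr4, the LPS receptor, at -1.96, whereas its co-receptor Cd14 stood at 3.54 and Traf6 at 2.40. Markers of other cells also differed between these arrays. Plasmacytoid DC markers had a median of 1.54, with Ly6d at 3.40 and Ccr9 at 3.09. NK cell markers had a median of 1.31, with Prf1 at 2.88 but Klrd1 at -3.86, and plasma cell markers of 0.94, with Jchain at 4.06. Mature neutrophil genes had a median of 0.71, with Slfn4 at 4.89 and Ccl6 at -2.81. The iron genes had a median of 1.14, with Hp (haptoglobin) at 5.04 and Tfrc, the transferrin receptor, at -1.82. Smaller medians were those of the regulatory genes (0.90), the NRF2 genes of the oxidative stress response (0.70) and the myeloid suppressor genes (0.63). Averaging probe sets brought Bub1 to -2.63, Tlr4 to -0.83, Ccr9 to 1.58, Prf1 to 1.43 and Tfrc to -0.58.

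In total 3847 of 11680 measured genes differed by at least 2-fold, 1179 higher and 2668 lower with LPS. The median gene differed by -0.14. With each array centred on its own median this became 0.25 and the split 2048 higher and 1774 lower, so the direction of the bulk of genes rests on the scaling. Apart from the T cell markers, each list above lay outside the 95% range of 10000 random lists of matched expression, at a percentile of 0.985 for the pattern recognition genes and at 99.7 or above or at 0 for the others. With the floor at the 75th percentile, plasma cell markers came inside that range, at 0.44 and a percentile of 93.2, as did pattern recognition genes, at a percentile of 5.35.

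The next comparison set wildtype mice given LPS and aPC against those given LPS. Among the genes lower in the LPS-aPC array than in the LPS array, Ifng had a difference of -5.28, Ctla4, an inhibitory T cell receptor, of -4.89, the chemokine Ccl22 of -3.03 and the costimulatory ligand Cd80 of -2.93. The fixed lists of T cell and NK cell markers had medians of 0.38 and -0.17, both inside the range of random lists. Procr, the receptor of aPC, stood at -3.31 and F2r at -1.75. Neutrophil genes were higher, with S100a9 and S100a8, the subunits of calprotectin, at 6.60 and 6.29, Chil3 at 5.46, the neutrophil granule gene Ngp at 5.21 and the collagenase Mmp8 at 4.70. B cell genes were higher too, among them Bank1 at 4.69 and Ms4a1, which encodes CD20, at 4.64. Clec4a3 at 4.95, Ifitm6 at 4.64 and Chil1 at 4.50 completed the highest differences. Sema4f at -5.29, Rufy3 at -4.91, Ccr9 at -4.86, Igha at -4.45, Pcyt1a at -4.26, Cirbp at -4.19, S1pr3 at -4.18 and Ilrun at -4.06 completed the lowest. Without probe sets ending in _x_at or _s_at, which can bind several transcripts, the difference of Ilrun turned to 1.19. With the mean of a gene's probe sets Rufy3 came to -2.44, Ccr9 to -1.73, Pcyt1a to -2.29, S1pr3 to -1.99, Ilrun to -1.44 and Cd80 to -1.72, and 12 of the 20 genes highest or lowest had an array at or under the floor.

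DC maturation genes had a median of -1.22, with 12 of 19 at least 2-fold lower and 0 higher. NF-kB targets had a median of -0.84, with 11 of 26 at least 2-fold lower, including Malt1 at -2.65 and Nfkbib at -2.11, against 1.93 for Irak3, an inhibitor of Toll-like receptor signalling. Class II genes had a median of 0.52, with H2-Ob at 2.02 and Lgmn at -1.72; their percentile of 98.9 came down to 94.5 after quantile normalization. Cell cycle genes had a median of 0.74, with Rrm2 at 1.89 and Ccne1 at -1.34, and pattern recognition genes of 0.66, with Clec4n at 2.31 and Traf6 at -3.95 (-2.51 as the mean of its probe sets). Interferon-stimulated genes had a median of -0.50 and inflammatory cytokines and chemokines of -0.08, both inside the range of random lists.

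The array with aPC carried more signal for several other cell types. Mature neutrophil genes had a median of 2.30 with 9 of 11 at least 2-fold higher, and secondary granule genes a median of 2.03 with 7 of 10. B cell markers had a median of 1.66 with 11 of 15 at least 2-fold higher, although Ighm, the IgM heavy chain, stood at -0.93. Macrophage and monocyte markers had a median of 1.32, led by the lysozyme Lyz2 at 2.78 and Cd68 at 2.17. Of lists that do not mark a cell type, complement genes had a median of 1.10 and iron genes of 0.59. Complement genes were led by Itgax, also a conventional DC marker, at 2.48 and properdin, Cfp, at 2.27 (1.29 as the mean of its probe sets). Plasmacytoid DC markers had a median of -0.98, with Siglech at -2.52, and plasma cell markers of -0.72, with Jchain at -3.72 and Prdm1 at -1.82. Some of these lists came inside the random range under an alternative: iron genes at 0.037 with the mean of probe sets, complement genes at 0.43 (percentile 94.6) with no floor, and plasma cell markers at -0.64 (percentile 15.0) with the higher floor. Of 11863 measured genes, 1616 were at least 2-fold higher and 1898 lower, or 966 and 1451 with the mean of probe sets and 1903 and 1545 after quantile normalization, so the majority turned with the scaling. Of the genes with several probe sets whose first probe set differed 2-fold, 80.2% had a second probe set on the same side and 45.1% one at least 2-fold so.

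**Figure D1:**
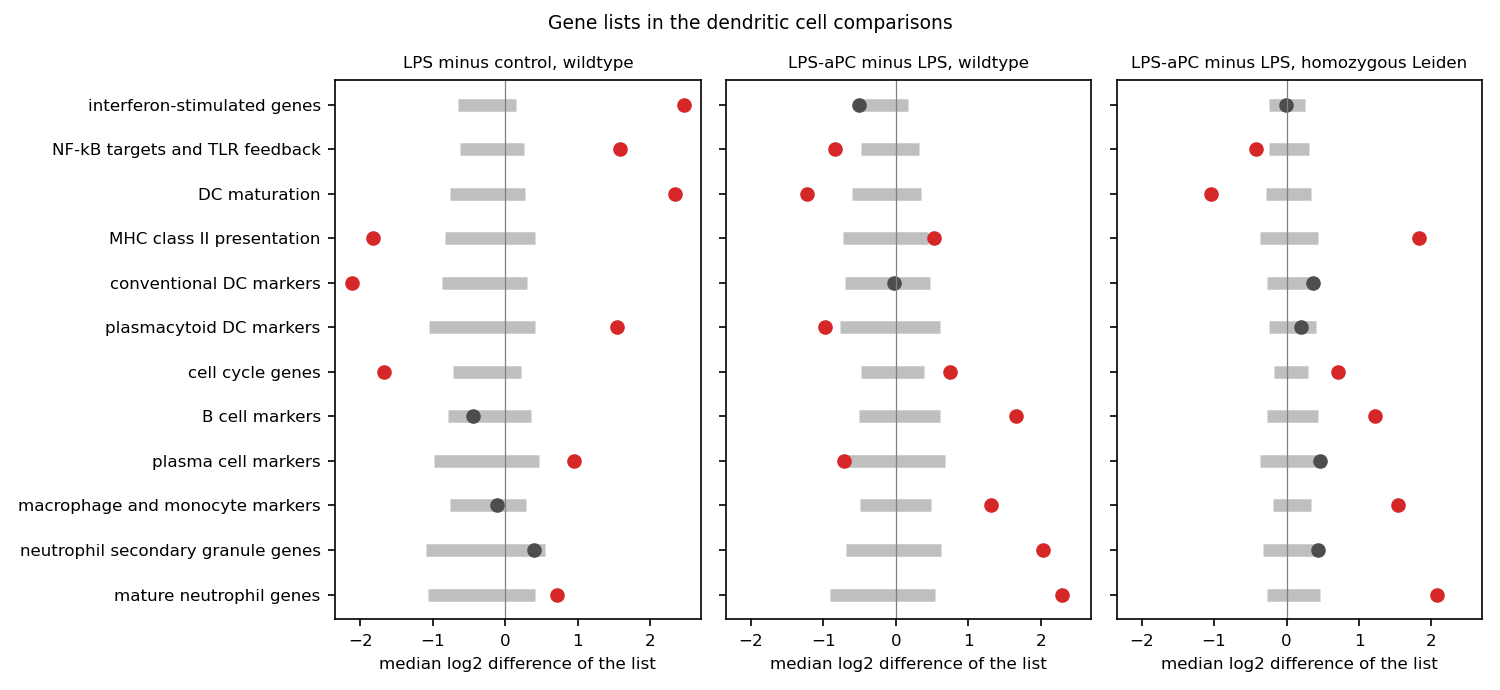
Medians of 12 gene lists in the 3 main DC comparisons, as log2 differences (points, red where outside the 95% range of 10000 matched random lists, which the grey bars show). DC maturation genes stood at 2.35 with LPS and at -1.22 and -1.05 with aPC in wildtype and homozygous Leiden mice. The LPS and wildtype aPC comparisons share the wildtype LPS array.

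The same question was asked in homozygous Leiden mice, with LPS-aPC and LPS arrays of their own. Ifng (-3.61), Ctla4 (-3.11), Sphk1 (-3.02), the vitamin D receptor Vdr (-2.999) and Cd80 (-2.93) were among the genes with the lowest differences. The others were Plagl1 at -3.52, B3gnt5 at -3.17, Cxcl3 at -2.88, Dgat1, which makes triglycerides, at -2.80 and Trim6 at -2.79. Among the highest were the C-type lectins Clec4a3 at 5.37 and Clec4a2 at 5.21, the lysozymes Lyz2 at 4.24 and Lyz1 at 3.92, and Alox5ap, needed for leukotriene synthesis, at 4.09. Ppp1r14a at 4.03, Bex6 at 3.97, Rgs18 at 3.95, Ifitm6 at 3.90 and Adgre4 at 3.89 completed that group. By the mean of a gene's probe sets Clec4a2 came to 2.74, Lyz1 to 2.61, Plagl1 to -1.24, B3gnt5 to -1.74, Cd80 to -1.64 and Trim6 to -1.56; 7 of the 20 genes had an array at or under the floor, and with it set to the floor Rgs18 came to 1.67 and Cxcl3 to -1.90. Procr had a difference of -1.94 and F2r of 0.16.

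DC maturation genes had a median of -1.05, with 11 of 20 at least 2-fold lower and 0 higher, Cd70 standing at -2.01. Class II genes had a median of 1.82, with 9 of 13 at least 2-fold higher, among them H2-Ob at 3.65 and Marchf1 at 2.82 (1.74 as the mean of its probe sets). Macrophage and monocyte markers had a median of 1.54, complement genes of 1.55, B cell markers of 1.23 and mature neutrophil genes of 2.07, the latter led by Trem3 at 3.53 and the formyl peptide receptor Fpr2 at 2.69. Secondary granule genes had a median of 0.435 with 3 of 9 at least 2-fold higher, inside the range of random lists. Pattern recognition genes had a median of 0.69, with Clec4n at 3.78 and Marco at 3.34 against -2.08 for Traf6 (as means of probe sets, 1.80 for Marco and -1.02 for Traf6), cell cycle genes of 0.71 and iron genes of 0.78. Of 11618 measured genes, 887 were at least 2-fold higher and 519 lower, which became 575 and 298 with the mean of probe sets, and 656 and 691 with the arrays centred, when the median gene went from 0.06 to -0.08.

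The arrays behind the aPC comparisons in wildtype and homozygous mice do not overlap, so their agreement owes nothing to a shared array. Across 11246 genes their differences correlated at 0.45. In both comparisons 395 genes were at least 2-fold higher, where 112 would be so for independent lists of the same sizes, and 351 were lower in both, where 83.0 would be. Only 27 genes were higher in wildtype and lower in homozygous mice, and 30 the reverse.

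A joint fit of the 6 DC arrays, chosen after the values were seen, treated LPS, aPC and genotype as additive effects. It assumes that aPC acts alike in wildtype and homozygous mice, and takes the departure from that as its only error, with 1 residual degree of freedom. By limma with Benjamini-Hochberg adjustment over 11815 genes, 19 differed with aPC at an adjusted p under 0.05, 13 higher and 6 lower. That error mixes the noise of the wildtype and homozygous pools with any true difference between the genotypes' aPC effects. No condition had replicate pools, so these p-values do not measure the spread between mice or pools of a condition. Chil3 and Trem3 of the neutrophil lists, Bank1 of the B cell list and Lyz2 of the macrophage list were among the 19. A change in the cells selected was not separated from a change within DCs. The estimates included 5.16 ± 0.38 for Clec4a3 (SE, limma adjusted p = 0.0161), 4.27 ± 0.39 for Ifitm6, -4.44 ± 0.48 for Ifng, 3.89 ± 0.47 for Bank1 and -2.93 ± 0.37 for Cd80 (SE, limma adjusted p = 0.0425 for each of these 4). For LPS and for heterozygous mice the fit has only 1 untreated and 1 heterozygous array, so no count of genes is given as a finding. Between homozygous Leiden and wildtype mice 1 gene differed, Gbp2b at 5.10 ± 0.39 (SE, limma adjusted p = 0.0222). On the heterozygous array Gbp2b lay at 4.44, under that array's floor of 4.62, against 9.27 and 8.74 on the homozygous arrays. With no floor, 0 genes passed for aPC or for homozygous mice. Under the other alternatives from 20 to 252 passed for aPC, with 73 higher and 78 lower when the arrays were centred.

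The difference between the genotypes' aPC effects was then taken directly, as the wildtype difference minus the homozygous Leiden difference. It was lowest for Ighg3 at -6.71, Jchain, the joining chain of IgA and IgM, at -6.50 and Igha at -6.08, while the fixed list of plasma cell markers had a median of -0.64, inside the range of random lists. Heavy chain genes are similar to each other, so single members are uncertain. Igha stood at 5.96 with LPS in wildtype mice and at -4.45 with aPC there. It stood at -4.64 and -4.88 in homozygous and heterozygous against wildtype mice under LPS. All these comparisons hold the wildtype LPS array, as this one does, so the differences are not independent. On the positive side Ngp stood at 4.85, S100a9 at 4.50 and Mmp8 at 3.95. The secondary granule list had a median of 1.77 with 7 of 10 members higher by at least 1 and 2 lower, and the mature neutrophil list one of 0.27, inside the range of random lists. Plasmacytoid DC markers had a median of -1.09, with Ccr9 at -4.84 and Siglech at -2.35, and class II genes of -1.16, with H2-Ab1 at -1.93 and H2-Eb1 at -1.67. Protein C and coagulation genes had a median of -0.88, from -2.04 for F10 and -1.91 for F2r to 1.90 for Tyro3 (0.38 with values under the floor set to it) and 1.61 for Mertk, both receptors of protein S and Gas6. Smaller medians were those of myeloid suppressor genes (-0.82), B cell markers (0.65), iron genes (-0.60) and macrophage and monocyte markers (-0.59), all of which came inside the random range under an alternative, at percentiles of 10.99 for suppressor genes with the mean of probe sets and, with the higher floor, of 97.15, 11.9 and 13.5. Procr stood at -1.37 and Hmox1, heme oxygenase 1, at -3.16. The other genes with the highest values were Speer4cos at 4.88, Sox11 at 4.79, the hematopoietic factor Nfe2 at 4.48, Tnc at 4.40, Ttll8 at 4.35, Id4 at 4.30, Nwd2 at 4.09 and Rad52 at 3.95. The other genes with the lowest were Ehd4 at -3.79, Zc3h13 at -3.72, Smarca2 at -3.69, Sash1 at -3.64, Clec10a at -3.63 and Ddx19b at -3.62. As the mean of probe sets, Sox11 came to 1.32, Tnc to 2.37, Id4 to 2.40, Ighg3 to -1.81, Ccr9 to -1.77, Zc3h13 to -2.31, Sash1 to -1.83 and Ddx19b to -1.23; 9 of the 20 genes had an array at or under the floor, and with such values set to the floor Nfe2 came to 2.055, Tnc to 2.64 and Id4 to 2.675. Of 12235 measured genes 1241 were higher by at least 1 and 1819 lower, or 701 and 1257 with the mean of probe sets, and 1482 and 1420 after quantile normalization, when the median gene went from -0.06 to 0.04. This quantity sums the noise of 4 arrays, and the probe sets of a gene correlated at 0.35 in it.

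Genotypes were compared in the LPS arrays, though the LPS dose of the heterozygous array is not given in the sources used here. In homozygous Leiden DCs, the genes furthest below wildtype DCs included Igha at -4.64, Jchain at -4.34, Igkv8-30 at -3.65 and Ighg3 at -3.54. Plasmacytoid DC genes were lower as well, with Ly6d at -4.35 and Ccr9 at -4.16, and Bst2, an interferon-induced surface protein, stood at -3.72. Hp stood at -4.49 and the galectin Lgals1 at -3.63, and Snord104 at -4.49. The highest differences were those of the guanylate-binding proteins Gbp2b at 5.44 and Gbp8 at 3.73, the long noncoding RNA Tug1 at 4.19, Tvp23b at 4.04, Crk at 3.81, Nlk at 3.70, Trim34a at 3.65, Tmem30a at 3.51, Dennd11 at 3.49 and Sox11 at 3.48. As the mean of probe sets, Tug1 came to 2.15, Crk to 0.83, Trim34a to 2.02, Tmem30a to 0.97, Dennd11 to 1.86, Sox11 to 0.84, Ccr9 to -1.64 and Ighg3 to -1.05; 5 of the 20 genes had an array at or under the floor, and with it set to the floor Dennd11 came to 2.20. Iron genes had a median of -1.43 with 8 of 11 at least 2-fold lower, Hmox1 reaching -2.91. Secondary granule genes had a median of -1.24, plasma cell markers of -0.93, macrophage and monocyte markers of -0.84 with Cd68 at -2.64, and class II genes of -0.80. Plasmacytoid DC markers stood at -0.79, mature neutrophil genes at -0.71, complement genes at -0.65, regulatory genes at -0.61, glycolysis and hypoxia genes at -0.595 and myeloid suppressor genes at -0.55. Inside the random range under an alternative came regulatory genes at -0.32 and suppressor genes at -0.36 with the mean of probe sets, complement genes at -0.42 after quantile normalization, and mature neutrophil genes, at a percentile of 9.835, with the higher floor. The NRF2 list had a median of -0.75, from -2.82 for Mt2 to 2.22 for Nfe2l2, the gene of NRF2 itself (0.18 as the mean of its probe sets). Procr differed by -0.34 and F2r by -0.38. Of 11552 measured genes, 1112 were at least 2-fold higher and 1355 lower, or 488 and 1006 with the mean of probe sets and 1306 and 1126 after quantile normalization, and of 1130 such genes with several probe sets 68.1% had a second probe set on the same side and 29.6% one at least 2-fold so.

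Heterozygous Leiden DCs after LPS were lower than wildtype DCs in many of those genes, with Hp at -5.77, Saa3 at -5.22, Jchain at -5.06, Igha at -4.88, Ly6d at -4.66, Ighm at -4.16, Igkv8-30 at -4.00 and Bst2 at -3.89. The long nuclear RNA Malat1 stood at -5.28 and Ankrd11 at -4.44; without probe sets ending in _x_at or _s_at Malat1 turned to 0.50. The highest differences were those of Tox3 at 4.47, Rnf180 at 4.27, Nkx1-2 at 4.05, Umad1 at 4.03, Lrif1 at 3.98, the zinc finger genes Zfp943 at 3.96 and Zfp52 at 3.91, the NK cell receptor Klrc1 at 3.78, Nxpe4 at 3.78 and Gbp8 at 3.77. Averaging probe sets brought Rnf180 to 2.40, Nkx1-2 to 1.58, Umad1 to 1.25, Zfp943 to 2.05, Zfp52 to 2.31, Klrc1 to 2.05, Malat1 to -2.96, Ankrd11 to -1.45 and Ighm to -2.35; 6 of the 20 genes had an array at or under the floor, and with it set to the floor Tox3 came to 2.32, Nkx1-2 to 2.31, Lrif1 to 2.11, Zfp943 to 2.43 and Nxpe4 to 2.07. Macrophage and monocyte markers had a median of -1.14, with the Fc receptor Fcgr1 at -3.16 (-1.43 as the mean of its probe sets) and Cd14 at -2.71. Iron genes had a median of -1.08, plasma cell markers of -1.17, class I presentation genes of -0.90 with Psmb10 at -1.90, and class II genes of -0.87. Secondary granule genes stood at -1.43, NRF2 genes at -0.80, complement genes at -0.67, plasmacytoid DC markers at -0.65 and mature neutrophil genes at -0.59. Class I genes came inside the random range at -0.60 (percentile 4.43) with the mean of probe sets, and complement genes at -0.18 (percentile 28.8) with the higher floor. Protein C and coagulation genes had a median of -1.14, with F10 at -3.40, Plaur, the urokinase receptor, at -1.90 and Procr at -1.57. NF-kB targets had a median of -0.51, while cell cycle genes had one of 0.79, with 8 of 27 at least 2-fold higher. Of 11695 measured genes, 1448 were at least 2-fold higher and 1301 lower, or 1715 and 1016 after quantile normalization, 1312 and 1416 with the arrays centred and 705 and 1011 with the mean of probe sets. Both genotype comparisons subtract the same wildtype LPS array, so what they share cannot be counted as independent. Heterozygous and homozygous Leiden arrays, compared after the values were seen, differed 2-fold in 909 of 11586 genes.

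**Figure D2:**
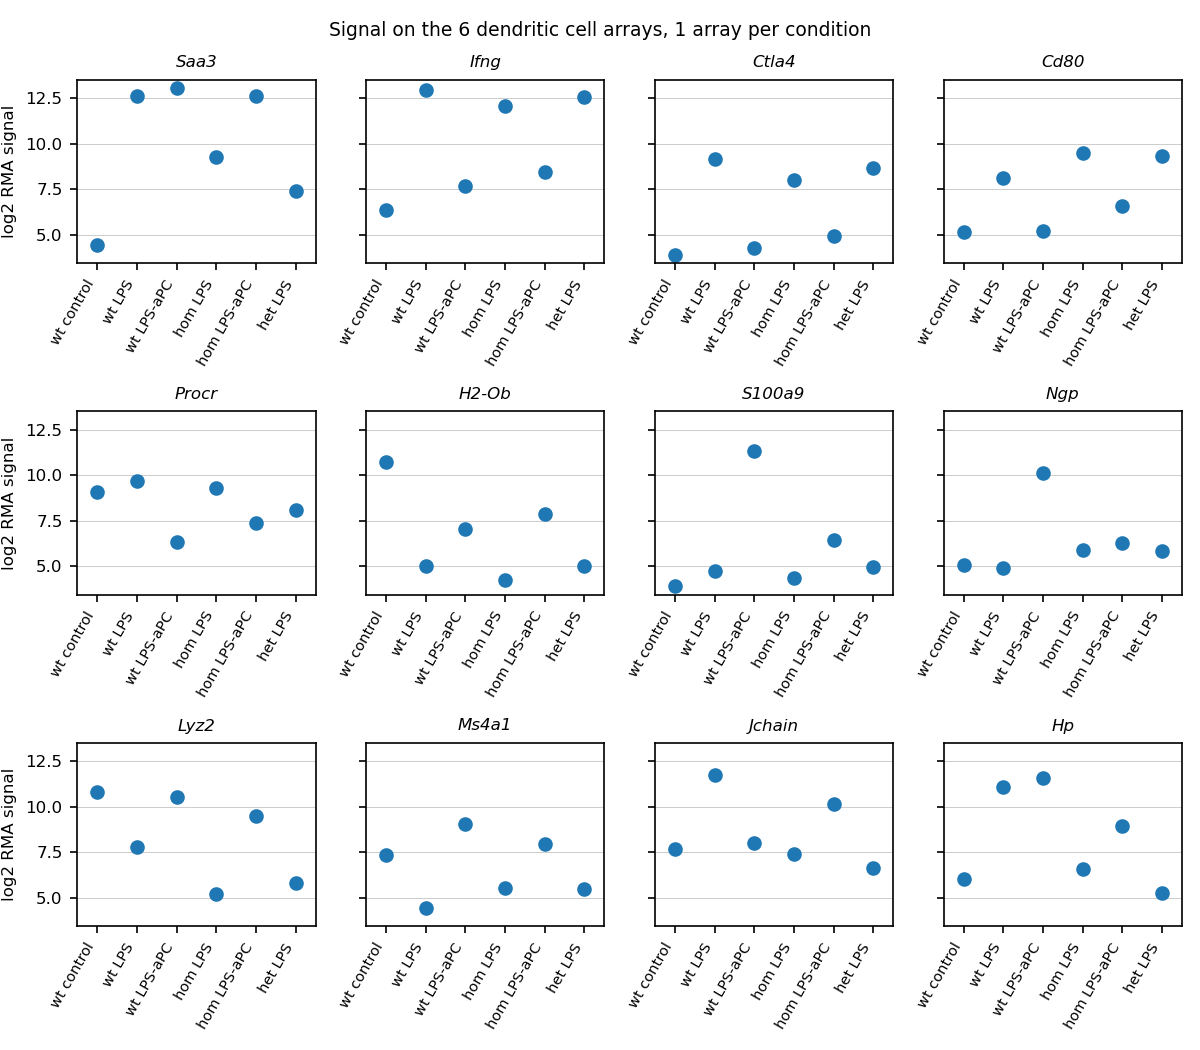
Log2 signal of 12 genes on the 6 DC arrays (1 point per array; wt, wildtype; hom and het, homozygous and heterozygous Leiden). Ifng was lower in both aPC arrays than in the LPS array of the same genotype, by -5.28 and -3.61.

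In RAW264.7 cells the first comparison was again LPS against the control. Cytokine and interferon-response genes were far higher after 3 h: Il6 by 9.39, Il1b by 7.91, the alarmin Il33 by 7.89, the chemokine Ccl5 by 7.49, and the guanylate-binding proteins Gbp2b, Gbp3 and Gbp2 by 7.58, 7.28 and 7.10. Serpinb2, an inhibitor of plasminogen activators, was higher by 8.44, Marcks by 7.65 and Ifi209 by 7.25. The lowest differences were those of Fam13c at -5.29, Hpgd, which degrades prostaglandins, at -5.22, Ranbp3l at -4.58, the retinoic acid receptor Rarb at -4.25, Rnf144b at -3.92, Slc16a12 at -3.90, Kbtbd11 at -3.88, Ung at -3.81, Zdhhc14 at -3.73 and Cytip at -3.69. Averaging probe sets brought Marcks to 4.14, Ifi209 to 4.71, Fam13c to -2.46, Rnf144b to -1.40, Kbtbd11 to -1.375 and Zdhhc14 to -2.36. Of these 20 genes, 13 had an array at or under the floor; with the control set to its floor, Il6 stood at 6.59, Serpinb2 at 6.78, Il33 at 6.42 and Gbp2b at 5.54, and with the LPS array so set Rarb stood at -2.81. All 36 measured interferon-stimulated genes were at least 2-fold higher, with a median of 4.28, as were 22 of 23 inflammatory cytokines and chemokines, with a median of 4.38. NF-kB targets had a median of 2.17 with 19 of 25 at least 2-fold higher, among them Acod1, which makes itaconate, at 5.24 and the cyclooxygenase Ptgs2 at 3.73. Regulatory genes had a median of 2.25, with Il10 at 5.74 and Socs3 at 5.16 against -1.97 for Klf4. Class I presentation genes had a median of 0.97, with Tap1 at 3.73 (0.97 as the mean of its probe sets) and Nlrc5 at 3.21, and DC maturation genes of 2.56, with Ccl22 at 4.85 and Cd40 at 4.54. Cell cycle genes had a median of -0.97, with 13 of 28 at least 2-fold lower. Apoptosis genes had one of 0.55, from 4.75 for Fas to -2.66 for Bcl2 (-1.58 as the mean of its probe sets). Myeloid suppressor genes stood at 1.10, mature neutrophil genes at 0.97 and NK cell markers, with 4 measured, at 0.69; with no floor the neutrophil list came to 0.065 and the NK cell list to 0.13, both inside the random range. F3, the gene of tissue factor, was higher by 3.97, Procr by 2.41 and Thbd, thrombomodulin, by 0.90, or 0.44 with the array under the floor set to it. Of 11229 measured genes, 657 were at least 2-fold higher and 782 lower, or 595 and 515 with the mean of probe sets, and 751 and 579 with the arrays centred, when the median gene went from -0.07 to 0.06.

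Adding aPC to LPS in normal plasma was compared with LPS alone in the same plasma. The lowest differences were those of Marcks, of -7.29 (-3.92 as the mean of its probe sets), Il6 of -7.10, the interferon-induced chemokine Cxcl11 of -6.46, Gbp2b and Gbp2 each of -5.84, Il33 of -5.82, Il10 of -5.54, Gbp3 of -5.44, Serpinb2 of -4.91 and Ccl22 of -4.79. The genes furthest above LPS alone included Hmox1 by 5.79, the iron exporter Slc40a1 by 4.53, the heme transporter Slc48a1 by 3.58, and Gclm and Gclc, which encode the enzyme that limits glutathione synthesis, by 3.51 and 3.48. Trib3 at 3.55 and Chac1 at 3.24, both genes of the amino acid stress response, Treml4 at 3.77, the chemokine receptor Cxcr4 at 3.73 and the Notch ligand Jag1 at 3.29 completed the highest differences; 7 of the 20 genes had an array at or under the floor, and with it set to the floor Treml4 came to 2.34 and Cxcr4 to 1.65. Procr was higher by 2.496 and Thbd by 0.92, while F3 stood at -3.76.

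Interferon-stimulated genes had a median of -2.05 with 31 of 36 at least 2-fold lower and 0 higher. Inflammatory cytokines and chemokines had a median of -3.16 with 20 of 23 lower, and NF-kB targets of -1.19 with 16 of 25 lower, Tnfaip3 at -4.21 and Cd69 at -3.90 (-1.38 with the array under the floor set to it) among them. DC maturation genes stood at -1.69, with Il15 at -4.26, class I presentation genes at -0.86, with Tap1 at -2.53 (-0.65 as the mean of its probe sets), and apoptosis genes at -0.59, with Tnfsf10 at -3.12 (-2.02 with the floor) and Casp4 at -2.56. Regulatory genes had a median of -1.05, with Socs3 at -3.87 but Klf2 at 1.99. NRF2 genes had a median of 1.37, with 11 of 17 at least 2-fold higher and 0 lower. Iron genes had a median of 0.58, from -2.40 for ceruloplasmin, Cp, upward, but of 0.11 with no floor, inside the random range. Of 11339 measured genes 392 were at least 2-fold higher and 537 lower, and of 450 such genes with several probe sets 96.4% had a second probe set on the same side and 60.9% one at least 2-fold so.

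A comparison chosen after the values were seen set the same LPS-aPC array against the untreated control. Interferon-stimulated genes remained above the control, with a median of 2.08 and 32 of 34 at least 2-fold higher, and cytokines and chemokines had a median of 1.58. NRF2 genes stood at 1.34 against the control, where LPS alone had left them at 0.25. Procr reached 4.91 and the cystine transporter Slc7a11 also 4.91.

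The last RAW264.7 comparison set LPS-aPC in plasma of homozygous Leiden mice against LPS-aPC in normal plasma. The genes furthest above normal plasma were Cxcl11 by 7.13, Il6 by 6.30, Marcks by 5.82 (2.865 as the mean of its probe sets), Cd69 by 5.75, Gbp2b by 5.61, Gbp2 by 5.58, Gbp3 by 5.53, Ccl12 by 5.09, the interferon-induced GTPase Iigp1 by 4.71 and Ccl5 by 4.66. The lowest differences included Hmox1 at -5.46, Slc40a1 at -5.13, Gclm at -3.31 and Slc48a1 at -3.25. Procr stood at -3.72 and Thbd at -1.45, and F3 was higher by 2.88. Treml4 at -4.24, the prostacyclin receptor Ptgir at -4.21, Cxcr4 at -3.91, Cd200r4 at -3.38 and Ypel5 at -3.29 completed the lowest differences; 10 of the 20 genes had an array at or under the floor, and with it set to the floor Cd69 came to 3.24, Treml4 to -2.33 and Cxcr4 to -1.64. Interferon-stimulated genes had a median of 1.84 with 29 of 36 at least 2-fold higher, cytokines and chemokines of 3.03 with 18 of 23, NF-kB targets of 1.57 with 17 of 25, DC maturation genes of 1.73 and class I presentation genes of 0.67. NRF2 genes had a median of -1.43 with 10 of 17 at least 2-fold lower, though Mt2 stood at 1.10, and iron genes of -0.86, or -0.10 with no floor, inside the random range. Of 11341 measured genes 450 were at least 2-fold higher and 407 lower. LPS in Leiden plasma without aPC was not analysed here, so what the plasma did by itself stays unknown. The plasma comparison subtracts the same LPS-aPC array of normal plasma that the aPC comparison adds. Opposite differences in these comparisons are therefore not independent. Set against LPS alone in normal plasma, a comparison chosen after the values were seen, LPS-aPC in Leiden plasma differed 2-fold in 200 of 11195 genes.

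**Figure D3:**
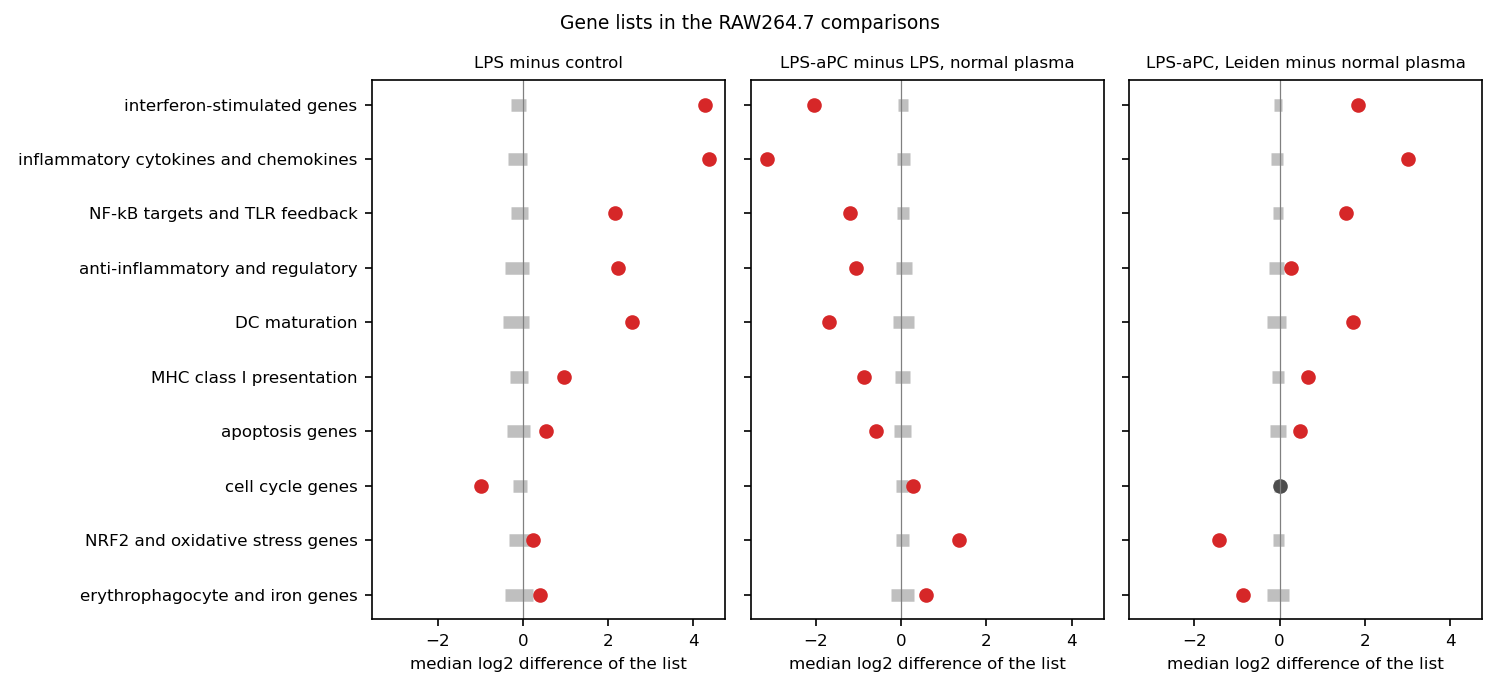
Medians of 10 gene lists in the 3 main RAW264.7 comparisons, as log2 differences (points, red where outside the 95% range of 10000 matched random lists, which the grey bars show). Interferon-stimulated genes stood at 4.28 with LPS, at -2.05 with aPC added and at 1.84 in Leiden against normal plasma. Neighbouring comparisons share an array, so these medians are not independent.

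**Figure D4:**
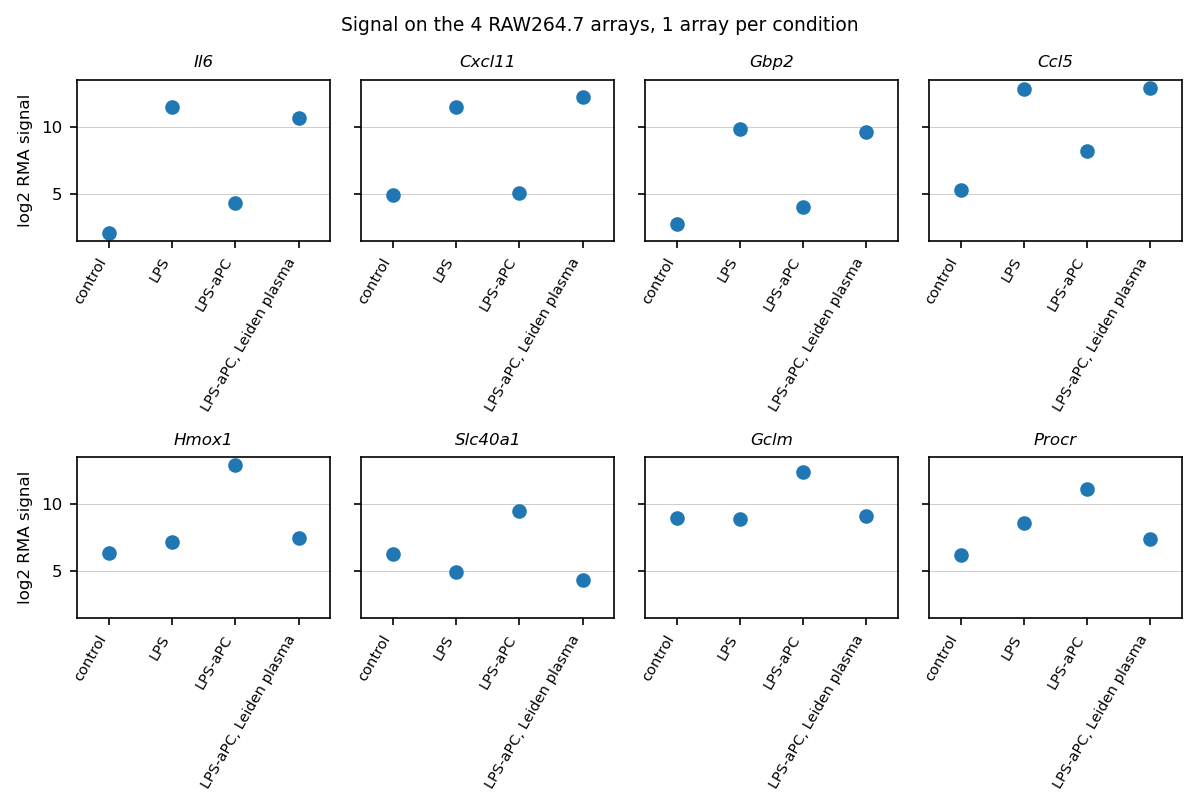
Log2 signal of 8 genes on the 4 RAW264.7 arrays (1 point per array). Hmox1 and Procr were highest, and Il6 and Cxcl11 far below the LPS array, on the array of LPS-aPC in normal plasma.

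Because the aPC comparisons subtract an LPS array, a list of LPS-induced genes chosen on that array would come out lower by chance. LPS lists were therefore taken from arrays that the followed comparison does not hold. The 657 genes at least 2-fold higher with LPS in RAW264.7 cells had a median of -0.47 in the wildtype DC aPC comparison, over 560 measured genes, and of -0.15 in the homozygous Leiden one. The 1179 genes higher with LPS in wildtype DCs had a median of -0.44 in the homozygous Leiden DC aPC comparison, where 268 were at least 2-fold lower and 43 higher. In RAW264.7 cells the same DC list had a median of -0.16 with aPC in normal plasma and of 0.10 in Leiden against normal plasma. All 5 medians lay beyond the 95% range of random lists. Genes at least 2-fold lower with LPS were followed in the same way after the values were seen: their medians were 0.07 and 0.15 for the RAW264.7 list in the wildtype and homozygous DC comparisons, the former inside the random range and -0.018 at the higher floor, 0.50 for the DC list in the homozygous comparison, and 0.11 and -0.08 for the DC list in the RAW264.7 comparisons, the latter inside the random range with 200 genes (-0.084). A list chosen after the values were seen, the RAW264.7 genes higher with LPS, had a median of 1.02 in Leiden against normal plasma, and across 11034 genes the LPS response and that plasma difference correlated at 0.63 without sharing an array.

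In the bone marrow set, Gr1/CD11b cells of infected recipients of a transfer without EPCR/F4/80-positive cells were compared with those of recipients of a complete transfer. The values of these 4 columns do not belong to the probe set IDs beside them, so no gene can be named. Their rows lie in descending order of the difference between the group means, from 2.62 in the first row to -5.05 in the last, and rise by 0.0015 at most from a row to the next. On these arrays 2 probe sets of the same gene correlated at 0.01 to 0.02, against 0.40 to 0.57 on the other 10. The row at the ID of Rplp0, a ribosomal protein gene with a mean of 13.25 in RAW264.7 cells, held a mean of 3.20. The arrays themselves were closely alike, with correlations of 0.995 and 0.997 within the groups and 0.990 to 0.991 between them, and a test by row does not need the IDs.

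By limma with Benjamini-Hochberg adjustment, 2440 of 22929 rows above the floor differed between the groups at an adjusted p under 0.05, 1354 higher and 1086 lower in the depleted transfer. With the arrays centred the split was 729 and 1394. Large differences ran nearly all one way: 221 of the rows that passed were at least 2-fold lower in the depleted transfer and 21 at least 2-fold higher, and at 4-fold the numbers were 64 and 3. Of these 221 and 64 lower rows, 120 and 23 lay above the array median on both depleted-transfer arrays, so many of the sizes rest on background. The lowest row went from 6.98 with wildtype transfer to 1.93 with depleted transfer, a difference of -2.705 with the latter set to the array medians (limma adjusted p = 0.00123). The next row lay above the median on all arrays and went from 10.48 ± 0.02 to 5.93 ± 0.07 (SD, n = 2 each), a limma difference of -4.55 ± 0.06 (SE, adjusted p = 0.000553). The row with the brightest signal among the 10 lowest went from 11.18 to 7.32 (limma adjusted p = 0.000553). The highest row went from 4.64 to 7.26 (limma adjusted p = 0.00425). With 2 arrays per group the number of calls was unstable: without either wildtype-transfer array 0 rows passed, and without either depleted-transfer array 29 or 16 did. With the replicate number as a block 288 passed. At an unadjusted p under 0.05, limma gave 7451 rows with all arrays, 6624 and 7073 without a wildtype-transfer array, and 4176 and 4019 without a depleted-transfer array.

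**Figure D5:**
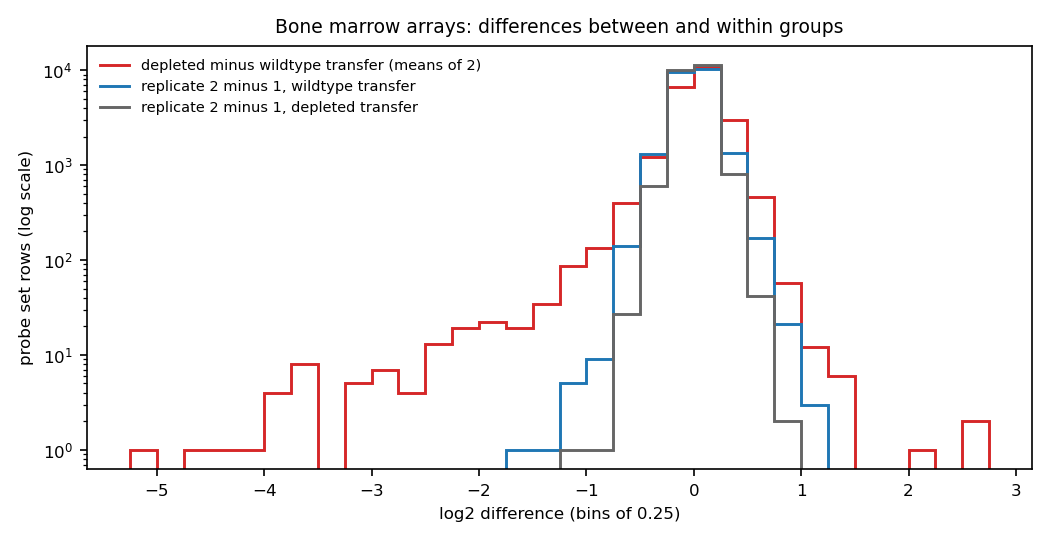
Number of bone marrow probe set rows (log scale) by log2 difference in bins of 0.25, between the group means (red) and between replicates (blue, wildtype transfer; grey, depleted transfer). The difference between groups reached -5.05.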

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

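All tests in this part were chosen after the results were seen. The genes named first lay at least 2-fold higher in a comparison and at least 2-fold lower in its counterpart in another genotype, plasma or cell type; these differences were not tested, since each condition had 1 array.

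With aPC, Igha stood at -4.446 in wildtype DCs and at 1.636 in homozygous Leiden DCs. The former subtracts the wildtype LPS array, on which Igha stood 5.957 above the control. Igha was among 30 genes at least 2-fold lower with aPC in wildtype and higher in homozygous DCs. Another 27 genes went the reverse way. Against LPS alone in normal plasma, RAW264.7 cells with LPS-aPC had Egr3 at -1.05 in normal and 3.005 in Leiden plasma, and Procr at 2.496 in normal and -1.22 in Leiden plasma. As the mean of its probe sets Egr3 stood at 1.519 in Leiden plasma, and in normal plasma its level of 4.685 lay under the floor of 4.869. With LPS, Il1b stood at -1.148 in DCs and 7.91 in RAW264.7 cells, Serpinb2 at -2.868 and 8.444, and Tlr3 at -5.215 and 3.998. With the array under the floor set to it, Serpinb2 in DCs stood at -0.649. The DCs came from mice after 16 h and the RAW264.7 cells from cultures of 3 h, so time and setting differ as well as cell type. With aPC in wildtype DCs and in RAW264.7 cells, Hmox1 stood at -1.772 and 5.79, Procr at -3.311 and 2.496, and Slc48a1 at -1.027 and 3.585. In homozygous Leiden DCs Hmox1 was higher with aPC, as in RAW264.7 cells, so its contrast between cell types does not extend to that genotype.

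Neutrophil genes were higher in the wildtype DC array with LPS-aPC. Of the measured members of the secondary granule and mature neutrophil lists, 76.2% (16 of 21) were at least 2-fold higher, which restates the pattern, so neutrophils among the cells selected for CD11c stay open. A lower share of DCs could raise every other cell type alike. The medians of 9 other cell type lists lay up to 3.02 apart (2.30 and -0.72). The highest was the mature neutrophil list, the pattern itself, and the lowest came inside the random range under some alternatives. Among the remaining lists, B cell markers at 1.66 and NK cell markers at -0.17 also differed, which argues against such a rise alike. Conventional DC markers had a median of -0.02, inside the random range. The mature neutrophil list was also higher with aPC in homozygous Leiden DCs, with a median of 2.07, but the secondary granule list stood at 0.435, inside the range of random lists. With 1 pool per condition, that effect and a difference in cell selection both stay open.

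The RAW264.7 array with LPS-aPC in normal plasma had lower LPS-induced genes and higher NRF2 genes than LPS alone. An unstimulated culture is argued against by the interferon-stimulated genes, whose median against the control was 2.08. A weaker LPS stimulus is argued against for the NRF2 genes, at 1.34 against the control where LPS alone stood at 0.25. For the LPS-induced genes it cannot be told apart from an effect of aPC, since both predict the median of -1.30 seen for genes chosen on the Leiden plasma array. Whether the factor V allele mattered stays open for the same reason: 200 genes differed 2-fold from LPS alone in Leiden plasma and 929 in normal plasma, with 1 pool each.

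The bone marrow values do not go with their probe set IDs. Probe sets of the same gene correlated at 0.0219 at most on these arrays and at 0.3999 or more on the others, which is consistent with rows ordered apart from the IDs. Noisy arrays are argued against by replicate correlations of 0.995 or more. An unlike cell type is argued against by the lowest probe set correlation of 0.0107, since probe sets of a gene go together in any cell. No biological explanation from the design was tested.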

How the results depend on the processing

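Tests with the heterozygous list, the Leiden-plasma list, the RAW264.7 list in the plasma comparison, genes lower with LPS, the 4 further comparisons the removal of cell type list members, arrays set to the floor and the additive fit were chosen after the results were seen.

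Counts of 2-fold genes stayed within 1.5 times under quantile normalization, centring, no floor and without _x_at or _s_at probe sets in all 13 comparisons of single arrays. At a threshold of 1.5, by construction, they were 2204 for LPS in DCs, 1721 and 509 for aPC in wildtype and homozygous DCs, 1354 for their difference, 970 and 1160 for homozygous and heterozygous against wildtype, 732, 453 and 397 for the RAW264.7 comparisons in order, and 209, 1660, 68 and 319 for the further ones. With the mean of probe sets they were 873 for aPC in homozygous DCs, 1958 for the difference, 1494 and 1716 for the genotypes, 412 for heterozygous against homozygous, 2466 for wildtype LPS-aPC against control and 132 for Leiden-plasma LPS-aPC against LPS, which the higher floor left at 126 with fewer genes. Of the list medians described, under alternatives that can move a median, 325 moved by more than the spread, 286 by less and 134 were identical; that spread is a gene's between single arrays, not a list's. Random lists without matching cannot move a median but can move a percentile. With them counted, a list came inside the random range in 39 of 870 pairs of list and alternative. These pairs fell in 23 of the 125 lists described. In the DC LPS response these were plasma cell markers and pattern recognition genes; with aPC in wildtype, class II, plasma cell, complement and iron genes; in the difference between genotypes, B cell, macrophage, myeloid suppressor and iron genes; in homozygous against wildtype, regulatory, mature neutrophil, myeloid suppressor and complement genes; and in heterozygous against wildtype, class I and complement genes. In RAW264.7 cells, iron, NK cell and mature neutrophil lists of the planned comparisons did so with no floor. Their values stand beside the results; with no floor, complement genes in heterozygous against homozygous DCs (0.0265), and B cell (-0.021) and iron (0.072) genes in RAW264.7 LPS-aPC against control, did so too. The spread comes from other cells, and signal near background limits faint genes.

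Of the values of named genes under an alternative, 939 moved by more than the spread, 804 by less and 8 changed sign; 912 were identical, mostly since the alternative could not move them. Among the 20 highest and lowest genes of the planned comparisons, from 1 to 9 were over 1.5 times smaller with the mean of probe sets, as the report gives by gene, and 5 to 13 had an array at or under the floor. With the mean of probe sets, Tlr7 (0.688) and Nfe2l2 (0.092) changed sign in the DC LPS response, Hif1a (-0.033) in homozygous and Nfe2l2 (-0.2675) in heterozygous against wildtype. Without _x_at or _s_at probe sets, Ilrun (1.187) did so with aPC in wildtype, Lyz1 (0.586) in the difference between genotypes, and Malat1 (0.503) and Rrm2 (-0.318) in heterozygous against wildtype. The cause was not tested.

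For followed genes higher with LPS, medians were, with no floor, -0.302 (RAW264.7 list, wildtype DC aPC); at the 75th percentile, -0.635 (the same), -0.5545 (DC list, homozygous), and -1.006 and -0.649 (heterozygous list, wildtype and homozygous); after quantile normalization, -0.3272 and -0.4725 (RAW264.7 and heterozygous lists, wildtype); with the mean of probe sets, -0.2828 and 0.205 (DC list, RAW264.7 aPC and plasma) and -0.6545 (heterozygous list, homozygous). Centred they were -0.2585 (RAW264.7 list, homozygous), -0.237 and -0.3895 (heterozygous list, wildtype and homozygous) and -1.091 (Leiden-plasma list). With 200 genes they were -0.2485 (RAW264.7 list, homozygous), -0.6405, 0.476 and -0.861 (DC list in RAW264.7 aPC, plasma and homozygous DCs), -1.406 and -1.248 (heterozygous list), -2.256 (Leiden-plasma list) and 2.049 (RAW264.7 list, plasma). For genes lower with LPS, quantile normalization gave 0.182 and 0.5107 (RAW264.7 and heterozygous lists, wildtype) and 0.7376 (heterozygous list, homozygous). Centring gave 0.0095 (RAW264.7 list, homozygous), 0.3745 (heterozygous list, wildtype) and 0.0125 (DC list, plasma). Centring shifts all genes of a comparison alike, but the lists were also chosen again on the centred arrays. The last list went from 2668 to 1774 genes. It stayed below random lists, whose median went from -0.053 to 0.035. Lists of 200 gave 0.26 (RAW264.7 list, homozygous), 1.342 (DC list, homozygous), 1.1555 and 1.668 (heterozygous list), 0.812 (Leiden-plasma list) and -0.688 (RAW264.7 list, plasma). The cause was not tested.

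The bone marrow count of 2440 became 547 with no floor, 3685 at the 75th percentile, 4748 with trend and robust, 5151 at an adjusted p under 0.1, and 288 with replicate number as a block. Leaving out 1 array gave from 0 to 29 by limma, the lone array being assumed to vary like the other group. Camera, fry, the mean of probe sets and the removal of _x_at and _s_at probe sets were not run for these arrays, since they need the IDs.

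The additive fit's 734, 19, 1 and 0 genes for LPS, aPC, homozygous and heterozygous mice each became 0 with no floor. For aPC they were 178 at the 75th percentile, 96 with the mean of probe sets, 107 after quantile normalization, 151 centred, 239 with trend and robust and 252 at an adjusted p under 0.1, where LPS gave 1392. Homozygous mice gave 3 at the 75th percentile and 5 with trend and robust, heterozygous mice 2 and 4, and 1 centred. Without any of the wildtype or homozygous LPS and LPS-aPC arrays, no residual degree of freedom is left. The untreated and heterozygous arrays, 1 of each, add nothing to the fit's error. Counts for LPS and for heterozygous mice therefore show only how the fit moved with the settings. They are not findings on genes that differ.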

Other observations

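All tests in this part were chosen after the results were seen.

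Wildtype DCs after LPS and aPC were also set against the untreated control. Neutrophil secondary granule genes had a median of 3.82 and mature neutrophil genes of 3.12, and interferon-stimulated genes of 1.82 with 29 of 36 at least 2-fold higher. Conventional DC markers stood at -1.51, class II genes at -1.30 and cell cycle genes at -1.15. Of 11944 measured genes 1026 were at least 2-fold higher and 2716 lower, or 1315 and 1792 after quantile normalization and 2291 and 1523 with the arrays centred, when the median gene went from -0.21 to 0.18.

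In heterozygous against homozygous Leiden DCs after LPS, cell cycle genes had a median of 0.92 with 10 of 27 at least 2-fold higher, complement genes of 0.61, or 0.0265 and inside the random range with no floor, and NK cell markers of 0.58. In RAW264.7 cells with LPS-aPC in normal plasma against the control, 370 genes were at least 2-fold higher and 402 lower, or 446 and 280 with the arrays centred, when the median gene went from -0.03 to 0.085.

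A hypothesis was that aPC lowers LPS-induced genes in DCs of both genotypes. Genes higher with LPS on the heterozygous array, which neither aPC comparison holds, had a median of -0.79 with aPC in wildtype mice, below the range of random lists, which the hypothesis needs. In homozygous Leiden mice their median was -0.53, also below that range, which argues against factor V Leiden removing the difference. The sizes depend on the scaling, which also changes the list, from 993 genes to 2081 with the arrays centred and 1326 after quantile normalization. The medians were then -0.237 and -0.3895 with the arrays centred, and -0.4725 and -0.4335 after quantile normalization. The list subtracts the wildtype control, as no heterozygous control was analysed here, and so mixes genotype with LPS. Markers of other cells were higher in the same comparisons, with medians in wildtype and homozygous mice of 2.30 and 2.07 for mature neutrophil genes, 1.66 and 1.225 for B cell and 1.32 and 1.54 for macrophage and monocyte markers. A change in the cells selected was not separated from a change within DCs, so the hypothesis stays open. Each comparison had 1 array per condition, and the 2 medians were not tested against each other.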
